A study of Mus musculus with 6 samples.

How the data were processed

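RNA from mouse cornea was measured by RNA sequencing in 6 libraries, 3 titled Control and 3 titled Cationorm. Per the labels' protocols, RNA was extracted with TRIzol, enriched for mRNA and made into Illumina TruSeq libraries, and the mice were male C57BL/6J animals aged 6 to 8 weeks. The deposited table holds raw whole-number read counts per gene symbol, with 1 column of counts per library, per the file headers. The submitters' processing notes list DESeq2 and the genome builds GRCm39 and mm39, with no role stated for any of them. The aligner, the counting tool, their versions, the annotation release and the strand setting are not given in the sources used here. Without a stated strand setting, reads from overlapping or antisense genes cannot be told apart, and genes with near-identical copies are treated as uncertain. The reference annotation at hand was of GRCm38, an older build, so it served only for gene names and neighbouring genes and no coordinates are given.

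Library columns were matched to samples by the library names in the labels, and the groups were taken from the titles. The labels give a single batch for all libraries. They do not state that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical. Total counts ran from 32486043 in Cationorm 1 to 39193311 in Control 1. A count of 0 allows a level of up to 0.0765 CPM (counts scaled to library size) in the deepest library and 0.0923 CPM in the shallowest, taking 3 counts as the limit, and these floors cover counting error only. The low counts of Muc16, Muc5ac and Il6 were even numbers in every library. If a fragment added more than 1 count, which is not stated, these floors are too low. Pearson's r of log2 CPM over genes lay between 0.978 and 0.984 within groups and between 0.967 and 0.990 across groups, and no pair of replicates differed by as little as sampling noise (chi-square per degree of freedom of at least 27.7).

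Counts were normalised by TMM and filtered with filterByExpr, which kept 18804 of 35673 genes, and 3247 genes had no count in any library. The kept genes held at least 99.9% of the counts of each library. Cationorm was tested against Control with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with no covariate and Benjamini-Hochberg adjustment at 0.05. Standard errors were derived from the fitted log2 fold change and the F statistic, and 95% intervals from the t distribution with the moderated degrees of freedom. The levels given are TMM-normalised CPM as mean ± SD over the libraries of a group. Gene lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, and again with the correlation estimated for each list and with fry, which asks whether a list's genes move on balance in 1 direction. Of 46 lists, 45 had at least 3 tested members. Each list's members were also adjusted over the list alone.

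The groups, the test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Under that rule, genes past the threshold would be named by size of change. Because fewer than 5 passed in either direction, the 5 genes with the smallest p in each direction were named instead, with a mean of at least 5 CPM, groups that did not overlap, and no predicted gene models. Results are also given for 11 genes of a fixed panel of corneal identity, barrier, mucin and inflammation, and 1 further gene of that panel is not reported here. Other genes given as examples for a list were chosen after their values were seen, from its members with small p or high abundance.

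The alternatives were DESeq2 size factors, upper-quartile factors, no filter, a stricter filter (at least 1 CPM in 3 libraries and 50 counts in all), DESeq2 1.42.0, limma-voom with and without sample weights, the replicate number as a block, each library left out in turn, abundant gene classes or markers of other cell types left out, and stricter thresholds. Robust dispersion estimation, and the level of the retina, lens, iris and pigment, or skeletal muscle list as a covariate, were added after seeing the data. The iris and pigment level was higher in every Cationorm library than in every Control library. As a covariate it overlaps with the group, so a call lost with it cannot show whether the list depends on it. The procedure was tested on simulated counts for the 18804 genes of this comparison, with 200 genes changed. It recovered 13.4% of the genes changed 1.5-fold, 37.3% of those changed 2-fold and 71.2% of those changed 4-fold, with 5 false calls. With a 1.3-fold change simulated in the tight junction list, that list was called with the preset correlation and with the estimated correlation (adjusted p = 0.0381), and 1 of the 44 other lists was called with the preset correlation. The simulated genes were drawn independently of each other, whereas the median estimated correlation within the real lists was 0.33. The simulation therefore does not show how either list test behaves with correlated genes. The other arms named in the study design were not analysed here.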

Results

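Corneal transcript levels were measured in 6 mouse libraries, 3 Control and 3 Cationorm. Cationorm is a cationic oil-in-water nanoemulsion used as an eye drop. The labels describe a contact lens dry eye model made with 0.1% benzalkonium chloride, a preservative that irritates the ocular surface, and lens wear for 6 h per day. Drops of 5 µL were then given for 14 days. All 6 libraries carry the same disease-model tag, so the labels do not settle whether Control was the untreated arm or an arm of the model, and Control is used here as the name in the titles. Depth was 39193311, 34742200 and 34589433 counts in Control 1 to 3 and 32486043, 38542164 and 37012638 counts in Cationorm 1 to 3.

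The comparison of Cationorm with Control addressed how corneal gene expression differed between the groups. No single gene passed the test, the panel genes of corneal epithelium, barrier and inflammation included. Krt12, the keratin of corneal epithelium, was at 8659 ± 268 CPM in Control and 8728 ± 304 CPM in Cationorm (mean ± SD, n = 3 each). The 3 gene lists with the smallest p were of neighbouring eye tissues. The retina list was lower in Cationorm with a median log2 fold change of -0.84, and the melanocyte, iris and ciliary body list was higher with a median of 0.90. Both passed the list test with the preset correlation (adjusted p = 7.84e-08 and 3.30e-11), and neither did with the correlation estimated (adjusted p = 0.8615 with an estimated correlation for each).

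The quasi-likelihood test of edgeR called 0 of 18804 genes, with a smallest adjusted p of 0.550. At an unadjusted p under 0.05 there were 1641 genes, 970 higher and 671 lower in Cationorm. DESeq2, run without filterByExpr, gave p-values for 32423 genes and called 64 genes, 57 higher and 7 lower. Its own default filter on mean count was left on, so it may have adjusted over fewer genes. Without filterByExpr edgeR called 0 of 32426 genes, which is therefore not a like-for-like comparison. With filterByExpr limma-voom called 0 genes with or without sample weights. The groups did not overlap in 2788 genes (14.8%), against an average of 10% by chance for 3 against 3. Genes vary together and no spread around that average was computed, so 14.8% is not shown to be an excess. Without Cationorm 3, edgeR called 350 genes, 335 of them lower and 12 of these in the retina list, against 8 genes without Control 3 and 1 gene without Control 2.

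The 5 genes with the smallest p in each direction did not pass (adjusted p = 0.550 for each). Their groups did not overlap, which was a condition for naming them. Higher in Cationorm were Rps27a, which encodes a fusion of ubiquitin and a ribosomal protein, Penk, the precursor of enkephalins, Clu, the chaperone clusterin, Slc13a4, a sulfate transporter, and Best2, a bestrophin channel. Their log2 fold changes were 0.89 ± 0.14 (SE) for Rps27a, 1.10 ± 0.18 for Penk, 0.50 ± 0.08 for Clu, 1.63 ± 0.27 for Slc13a4 and 1.44 ± 0.24 for Best2. Clu was the most abundant of these, at 594 ± 57.5 CPM in Control and 837 ± 35.6 CPM in Cationorm (SD, n = 3). DESeq2 called all 5 of these genes. Lower in Cationorm were Sarnp (-0.85 ± 0.11), Snhg20 (-0.65 ± 0.13), Ptbp2 (-0.47 ± 0.10), Crebzf (-0.39 ± 0.09) and Erdr1y (-2.29 ± 0.52). Of these, DESeq2 called Sarnp and Snhg20. The values of 3 of the 10 genes are uncertain: Rps27a has processed pseudogenes, Sarnp overlaps neighbouring genes in the GRCm38 annotation, and Erdr1y has a near-identical copy, Erdr1x.

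**Figure D1:**
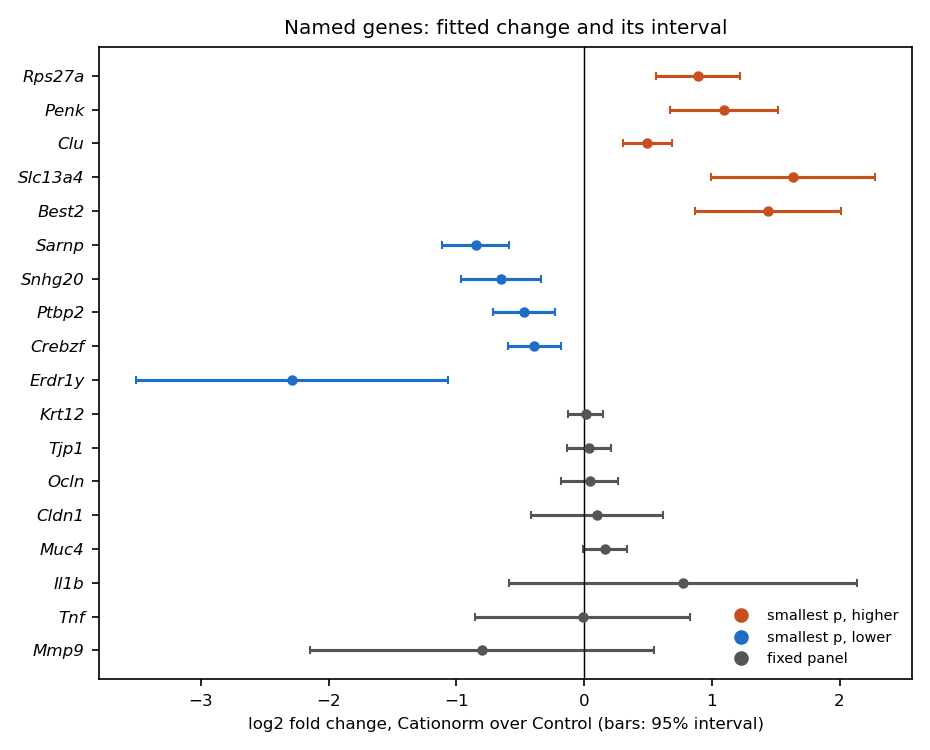
Fitted log2 fold change (Cationorm over Control, x axis) of the 10 genes with the smallest p and of the 8 tested panel genes given here (y axis), as points with 95% intervals as bars. The intervals of these 8 panel genes span 0. Those of the 10 other genes do not, which follows from picking them for small p, and their adjusted p was 0.550.

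Panel genes of the barrier differed by less than the test could separate from the spread between libraries. The log2 fold change (95% interval) was 0.01 (-0.12 to 0.15) for Krt12, 0.04 (-0.13 to 0.21) for the junction scaffold Tjp1, 0.04 (-0.18 to 0.27) for occludin (Ocln), 0.10 (-0.42 to 0.62) for claudin 1 (Cldn1) and 0.17 (-0.00491 to 0.34) for the membrane mucin Muc4. Inflammatory genes varied widely between libraries. Il1b was at 0.687 ± 0.250 CPM in Control and 1.18 ± 0.713 CPM in Cationorm, and Mmp9, a matrix protease, was at 2.49 ± 1.57 and 1.43 ± 0.925 CPM. Tnf was at 17.7 ± 9.04 and 17.5 ± 3.13 CPM. Adjusted p was 0.550 for Muc4, 0.629 for Il1b, 0.618 for Mmp9 and 0.993 for Tnf. Muc16 and Muc5ac had at most 4 counts in any library and Il6 at most 18, and these genes were removed by the low-count filter, so the main fit did not test them.

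Of the 45 gene lists, 13 were called higher and 1 lower in Cationorm with the preset correlation. With the correlation estimated, 0 lists were called (camera, smallest unadjusted p 0.0697, smallest adjusted p 0.8615), and fry called 0 (smallest adjusted p 0.523). With edgeR no list had a member that passed over all genes, whereas DESeq2 called 7 members of 6 lists over all genes, all higher in Cationorm: Rps27a, Clu, Myl9 (adjusted p = 2.87e-05), Acta2 (0.000642), Sod3 (0.00555), C4b (0.0122) and Col9a2 (0.0351). Other counts of list members past the threshold are from edgeR, in which 6 lists had at least 1 member past the threshold when adjusted over the list alone.

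Transcripts in the lists for other eye tissues were present in every library at levels that differed between libraries. Of 15 retina genes, 13 were lower in Cationorm, and 0 passed over all genes or adjusted over the list alone. Recoverin (Rcvrn), a calcium sensor of photoreceptors, had a log2 fold change of -1.02 ± 0.36 (SE), at 98.6, 107 and 71.4 CPM in Control 1 to 3 and 32.0, 29.9 and 74.4 CPM in Cationorm 1 to 3. The median of the retina list was -1.56 without Cationorm 3 and -0.55 without Cationorm 2, and with the preset correlation the list was called in both fits, as it was with the iris and pigment level as a covariate, added after seeing the data (median -0.271, adjusted p = 0.00666). With the correlation estimated, the list was not called with all 6 libraries (adjusted p = 0.8615). The retina list held 0.731 ± 0.142% of the counts in Control and 0.406 ± 0.270% in Cationorm. Of 13 melanocyte, iris and ciliary body genes, 12 were higher in Cationorm (adjusted p = 3.30e-11 with the preset and 0.8615 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone. Among them, the pigment enzyme Dct had a log2 fold change of 0.98 ± 0.32 (SE), the pigment cell regulator Mitf 0.65 ± 0.19 and the collagen gene Col9a2 1.02 ± 0.27. Dct was at 226, 210 and 490 CPM in Control 1 to 3 and at 687, 587 and 556 CPM in Cationorm 1 to 3. All 16 lens genes were higher in Cationorm (median 0.98, adjusted p = 4.49e-05 with the preset and 0.8615 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone. The lens list held 0.0118% of the counts in Control 1 and 0.864% in Cationorm 3, and its call was lost without either library (medians of 0.411 and 0.413), while without Control 2 the median was 1.65. It was 1.95 with limma-voom, 2.62 with sample weights and 1.81 with the replicate block, and the list was called in each. The vascular and lymphatic endothelium list had 11 of 13 genes higher (median 0.42, adjusted p = 0.00452 with the preset and 0.8615 with an estimated correlation), among them Flt4, Cdh5 and Tek. Its median was 0.181 without Control 2, where the call was lost, 0.27 without Control 1 and 0.788 without Control 3. With the retina level as a covariate, its call was lost (median 0.121, adjusted p = 0.0622), and with the iris and pigment level it was called in the opposite direction (median -0.24, adjusted p = 0.00888). The corneal endothelium list had 9 of 11 genes higher (median 0.08, adjusted p = 0.0417 with the preset and 0.8615 with an estimated correlation), and lost its call without any 1 of Control 2, Control 3, Cationorm 1 or Cationorm 3, with limma-voom sample weights (adjusted p = 0.115) and with the iris and pigment covariate (median 0.136, adjusted p = 0.0639). Its median ran from 0.023 without Cationorm 1 to 0.146 without Control 1, with 0.0355 without Control 3 and 0.144 without Cationorm 3, and was 0.178 with the lens covariate and 0.131 with the retina covariate, where the list was called.

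**Figure D2:**
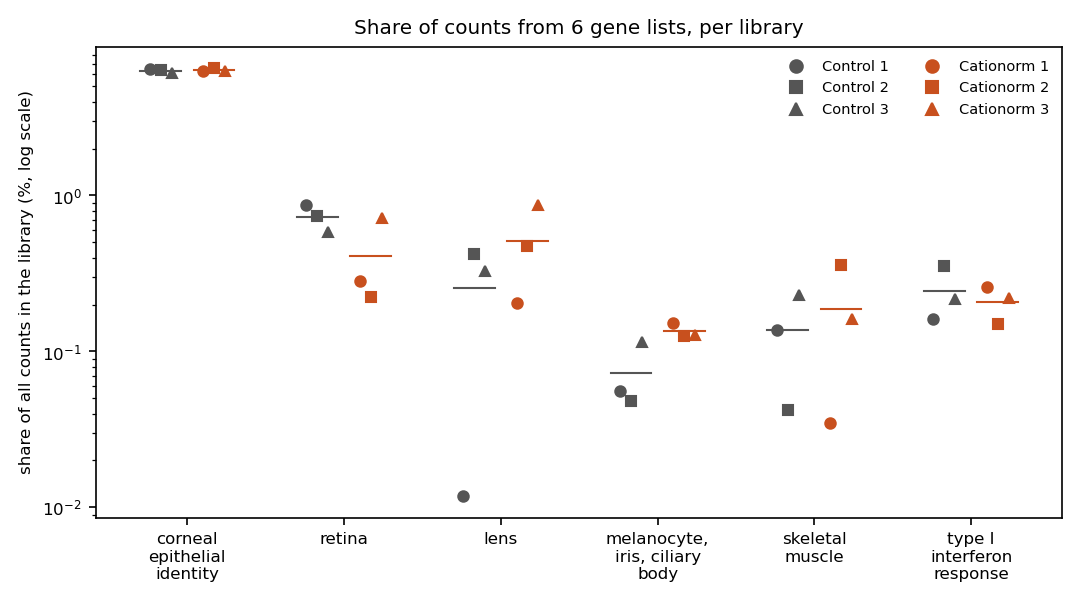
Share of all counts in a library (y axis, percent, log scale) from 6 gene lists (x axis), with a symbol per library and a line at each group mean. Corneal epithelial genes held between 6.07% and 6.53% in every library, whereas the lens list ran from 0.0118% to 0.864% and the retina list from 0.222% to 0.869%.

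The 3 lists of epithelial junctions and basement membrane attachment were called higher in Cationorm with the preset correlation, with small medians. The hemidesmosome and basement membrane list had 14 of 15 genes higher (median 0.16, adjusted p = 0.000606 with the preset and 0.8615 with an estimated correlation), with 0.87 ± 0.25 (SE) for the basement membrane protein Nid2, 0.18 ± 0.06 for integrin β4 (Itgb4) and 0.33 ± 0.10 for perlecan (Hspg2). The desmosome and adherens junction list had 16 of 21 higher (median 0.06, adjusted p = 0.0417 with the preset and 0.8615 with an estimated correlation), with 0.24 ± 0.07 for periplakin (Ppl), 0.21 ± 0.06 for desmoplakin (Dsp) and 0.27 ± 0.08 for α-catenin (Ctnna1). Its call was lost without Control 3, Cationorm 1 or Cationorm 2 and with the skeletal muscle level as a covariate (adjusted p = 0.061), and its median was 0.0922 without Cationorm 3 and 0.105 with limma-voom sample weights. The tight junction list had 15 of 17 higher (median 0.10, adjusted p = 0.03155 with the preset and 0.8615 with an estimated correlation) and lost its call without Control 2 (median 0.0616) or Cationorm 2, and its median was 0.158 without Control 3. In these 3 lists 0 genes passed over all genes and 0 when adjusted over the list alone. With the iris and pigment level as a covariate, none of the 3 lists was called (medians of 0.0588, 0.0627 and 0.0218, adjusted p = 0.252, 0.244 and 0.763 in the same order). The same held with the retina level (medians of 0.0781, 0.00186 and 0.0498, adjusted p = 0.179, 0.59 and 0.815). The iris and pigment level separated the groups without overlap, so a call lost with it as a covariate does not show a cause.

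Of 3 lists of fatty acid and cholesterol metabolism, 2 were called higher. Of 25 genes of fatty acid oxidation and PPAR targets, 22 were higher (median 0.25, adjusted p = 0.000215 with the preset and 0.8615 with an estimated correlation), with 0.84 ± 0.24 (SE) for the lipid droplet protein Plin4 and 0.25 ± 0.08 for the β-oxidation enzyme Hadhb. This median was 0.129 without Control 2, 0.381 without Control 3 and 0.136 without Cationorm 2 (adjusted p = 0.0482). The mean log2 CPM of the oxidation list was highest in Cationorm 2 (4.325), then in Control 3 (3.985), as was that of the skeletal muscle list (7.318 and 6.467). All 18 muscle genes were higher in Cationorm, and that list was not called (median 0.34, camera adjusted p = 0.4506). With the skeletal muscle level as a covariate, the oxidation list kept its call. Of 22 cholesterol biosynthesis genes, 19 were higher (median 0.13, adjusted p = 0.0147 with the preset and 0.8675 with an estimated correlation), among them Lss (0.29 ± 0.10) and the transcription factor Srebf2 (0.23 ± 0.08), and the call was lost without Cationorm 2 (median 0.0777), while the median was 0.0725 without Control 2. The fatty acid synthesis list had 16 of 20 genes higher and was not called (median 0.10, adjusted p = 0.0885). In these 3 lists 0 genes passed over all genes and 0 when adjusted over the list alone. With the iris and pigment level as a covariate, the calls of the oxidation and cholesterol lists were lost (medians of 0.056 and -0.00501, adjusted p = 0.777 for each). With the retina level the cholesterol list lost its call (median -0.00481, adjusted p = 0.988), and the oxidation list was called with a median of 0.109 (adjusted p = 0.0462).

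The myofibroblast and fibrosis list had 16 of 21 genes higher (median 0.20, adjusted p = 0.000266 with the preset and 0.8615 with an estimated correlation). Smooth muscle actin (Acta2, 0.96 ± 0.22 SE), the myosin light chain Myl9 (1.04 ± 0.19), calponin (Cnn1, 0.82 ± 0.23) and Tgfb2 (0.59 ± 0.16) were the 4 members past the threshold when adjusted over the list alone, and 0 passed over all genes. Acta2 was at 46.02, 55.3 and 81.6 CPM in Control 1 to 3 and 142, 108 and 107 CPM in Cationorm 1 to 3, and the iris and pigment list was likewise highest among the Control libraries in Control 3 (0.115% of counts, against 0.0560% and 0.0481%), as were the vascular endothelium and skeletal muscle lists. With the iris and pigment level as a covariate, the call of the list was lost (median 0.121, adjusted p = 0.0507). Ccn2, a matricellular growth factor of the same list, went the other way (-0.66 ± 0.23). The oxidative stress list had 18 of 25 higher (median 0.05, adjusted p = 0.0147 with the preset and 0.8615 with an estimated correlation), with 0.54 ± 0.11 for superoxide dismutase 3 (Sod3), the 1 member past the threshold when adjusted over the list alone, and 1.18 ± 0.34 for Gpx3. It lost its call without Cationorm 2 and with the iris and pigment covariate (median 0.0213, adjusted p = 0.182) or the retina covariate (median -0.0232, adjusted p = 0.294). Its median was 0.0343 without Cationorm 1, 0.0948 without Cationorm 3 and 0.0848 with limma-voom sample weights.

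The immediate early list, which responds to handling, had 14 of 19 genes higher (median 0.19, adjusted p = 0.00705 with the preset and 0.8615 with an estimated correlation), with 0.86 ± 0.31 (SE) for Fosb, and lost its call without Control 1 or Cationorm 2 (median 0.122). Its median was 0.31 without Control 3 and 0.291 without Cationorm 3, and its call was lost with the covariates of iris and pigment (median -0.0611, adjusted p = 0.763), retina (median -0.0269, adjusted p = 0.874) and lens (median 0.156, adjusted p = 0.0725). The cell cycle list had 19 of 24 higher (median 0.11, adjusted p = 0.03815 with the preset and 0.899 with an estimated correlation), with 0.30 ± 0.12 for the proliferation marker Mki67. Its call was lost without Cationorm 1 (median 0.0479), without Control 3 (median -0.0221) and with the retina covariate (median 0.0943, adjusted p = 0.199), and its median was 0.241 without Control 2 and 0.514 with the iris and pigment covariate. In both lists 0 genes passed over all genes and 0 when adjusted over the list alone.

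The other 31 lists tested were not called. Corneal epithelial identity (median 0.04, adjusted p = 0.255) held 6.30 ± 0.214% of counts in Control and 6.35 ± 0.157% in Cationorm, with Clu the 1 member past the threshold when adjusted over the list alone. The apoptosis list (median 0.04, adjusted p = 0.548), the antigen presentation list (median -0.16, adjusted p = 0.183) and the meibomian and sebaceous gland list (median 0.16, adjusted p = 0.403) had 0 such members. The complement list had C4b (0.69 ± 0.17 SE), the ion and water transport list the sodium channel subunit Scnn1a (0.29 ± 0.07) and the ribosomal protein list Rps27a as their 1 member past the threshold when adjusted over the list alone. Median, mean and test differed in sign in 5 lists, none of them called. These were membrane mucins (median -0.03, mean 0.05, tested higher), inflammatory cytokines and NF-kB (median -0.00417, mean -0.04, tested higher), stress keratins and alarmins (median -0.000255, mean 0.09, tested higher), macrophages and monocytes (median -0.00657, mean -0.01, tested higher) and neurotrophic factors (median 0.03, mean -0.03, tested higher).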

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

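The covariate fits and robust dispersion estimation were chosen after the result was seen, and the other settings were planned. The count of 0 genes held under every setting except DESeq2 (64 genes, 57 higher and 7 lower) and the fits without 1 library, which gave from 0 to 350 genes, 0 to 15 higher and 0 to 335 lower. The DESeq2 setting changed both the test and the gene set, with p-values for 32423 genes against 18804 in the main fit. DESeq2 also applied its own default filter on mean count before adjustment. Beside the 14 lists, 6 were called with the retina level as a covariate (5 of the 14 among them), 9 with iris and pigment (4 of the 14), 0 with an estimated correlation and 0 with fry. Without 1 library, 10 to 16 were called, with 9 to 12 of the 14 among them. The replicate block gave 0 genes and 14 lists and changed the sign of Tnf (0.0944). Same-numbered libraries did not deviate together (correlations of -0.18, -0.31 and -0.16), so these values gave no sign of pairing. So few libraries, with varying shares of the lens, muscle and retina lists, cannot exclude it. None of the 10 genes with the smallest p changed sign, but log2 fold changes shrank to 0.68 for Penk, 1.07 for Slc13a4 and -0.308 for Ptbp2 with the retina covariate and to 0.289 for Clu, 1.05 for Slc13a4 and -0.207 for Crebzf with iris and pigment. Without 1 library, log2 fold changes ran from -0.0326 to 0.0293 for Krt12, -0.00583 to 0.0920 for Tjp1, -0.0655 to 0.102 for Ocln, -0.0519 to 0.359 for Cldn1, 0.104 to 0.218 for Muc4, 0.376 to 1.19 for Il1b, -1.47 to -0.156 for Mmp9 and -0.323 to 0.417 for Tnf. With the retina covariate the sign turned for Krt12 (-0.00645), Tjp1 (-0.0567), Ocln (-0.0939), Mmp9 (0.166) and Tnf (0.0638), and it turned for Ocln with iris and pigment (-0.0806) and for Cldn1 with lens (-0.00704). Muc4 was 0.0866 with retina and 0.0179 with iris and pigment. Tnf was 0.122 with limma-voom, 0.100 with sample weights, 1.23 with iris and pigment and 0.0697 with skeletal muscle. The list medians became -0.24 for vascular endothelium with iris and pigment (called lower), -0.0269 and -0.0611 for immediate early genes with retina and with iris and pigment, and from -0.0221 to 0.241 for cell cycle without 1 library, and the lens test turned with its own level as covariate (median 0.0342). Genes at an unadjusted p under 0.05 in edgeR numbered 351 with the iris and pigment covariate and 477 with retina, against 1641 in the main fit. The iris and pigment level overlaps with the group, so calls lost with it cannot be read as due to it. The cause of these changes was not tested. Il1b gave no value under the stricter filter, nor did genes or lists under the setting that left them out. Muc16, Muc5ac and Il6 were removed by the low-count filter of the main fit, and no values for them from the fit without that filter are given here.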

Other observations

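Every test of an explanation given here was chosen after the result was seen. The keratocyte and stromal matrix list had 7 of 20 genes higher and 13 lower in Cationorm and was not called (median -0.05, adjusted p = 0.4996). Keratocan (Kera, log2 fold change -0.83 ± 0.28 SE), lumican (Lum, -0.66 ± 0.27) and Angptl7 (-0.72 ± 0.28) were lower in Cationorm, while Ptgds, a prostaglandin D synthase, was higher (0.999 ± 0.32), with 0 genes past the threshold when adjusted over the list alone and an adjusted p of 0.550 each. These genes were chosen after their values were seen. Type I interferon genes varied between the libraries of both groups: the list held 0.352% of the counts in Control 2 and 0.259% in Cationorm 1, and from 0.149% to 0.219% in the other libraries. The skeletal muscle list held 0.361% in Cationorm 2 and 0.0350% in Cationorm 1, and Myh13, a myosin of extraocular muscle, was at 82.1 CPM in Cationorm 2 and at most 4.15 CPM in the other libraries. Without Cationorm 3, 289 of the 335 genes called lower were those in which that library stood at or above the lowest Control library.

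With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For the count of genes past the threshold, the real split gave 0, so all 10 of the 10 splits gave as many by construction and the comparison says nothing about chance, and the highest other gave 1. For the lists called with the preset correlation, 5 of the 10 splits gave at least the 14 of the real split, and the highest other gave 16. The split of Control 1, Control 2 and Cationorm 3 against the rest had 2931 genes at an unadjusted p under 0.05, against 1641 in the real split and from 215 to 1211 in the other 8 splits.

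In Cationorm 13 of 15 retina genes were lower and 12 of 13 iris and pigment genes higher, with 0 of them past the threshold in edgeR and both list calls lost with an estimated correlation (adjusted p = 0.8615). Treatment as the origin stays open: the larger range within a group was 1.77 times the group difference for the retina list and 1.17 times for the iris and pigment list, but in the other group the range was smaller than the difference, and every Cationorm library lay above every Control library for iris and pigment. Iris and pigmented tissue carried along in varying amounts is a candidate explanation for its list: 1 common factor held 94.4% of its variance between libraries, above the 95th percentile of matched random lists (87.6%). Of 56 other genes that DESeq2 called higher, 87.5% were highest among the Control libraries in Control 3, against a median of 35.7% in matched random genes. The random genes were matched on abundance only, not on a group difference. Of the Control libraries, Control 3 had the highest Pearson's r with Cationorm 1, 2 and 3 (0.9781, 0.9845 and 0.9897). Genes picked as higher in Cationorm may peak in Control 3 whatever their origin, so this contrast cannot show an origin in iris tissue. Among the Cationorm libraries 75% were lowest in Cationorm 3, with no random share computed. By mean log2 CPM the iris and pigment level was slightly lower there (5.115) than in Cationorm 2 (5.173), with 5.409 in Cationorm 1. By share of counts it was lowest in Cationorm 2 (0.126%, against 0.127% in Cationorm 3). The iris and pigment level therefore does not single out Cationorm 3. Besides iris and pigment, 7 of 15 lists of other cell types were also highest in Control 3 among the Control libraries, vascular endothelium and skeletal muscle among them. The skeletal muscle list held 0.0350% of counts in Cationorm 1 and 0.162% in Cationorm 3, which argues against muscle as the origin of the genes lowest in Cationorm 3. Iris tissue cannot be told apart from the others of these lists, vascular endothelium included, as the origin. For carried retina, 1 factor held 84.3% over the list and 87.0% over its photoreceptor genes, below the 95th percentiles of 92.0% and 93.4%, so it cannot be told apart from the common variation of these libraries, and whether corneal cells express the genes of either list, all above 1 CPM in every library, was not tested.

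Lars2, a mitochondrial leucyl-tRNA synthetase, was at 1531 CPM in Cationorm 1 and between 64.2 and 299 CPM in the other libraries. A candidate explanation is ribosomal RNA counted under this gene. The ratio of the ribosomal RNA gene Rn18s-rs5 to Lars2 kept an SD of only 0.106 on the log2 scale over the 6 libraries, while Rn18s-rs5 itself ran from 863 to 23620 CPM. No biological explanation was tested.

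Rps27a was higher in Cationorm by 0.89 on the log2 scale, while its pseudogenes Rps27a-ps2 (-0.40) and Rps27a-ps3 (-0.58) were lower, none past the threshold. The summed count of Rps27a and the pseudogenes named for it, 4 genes in all, was still higher, by 0.538 (95% interval 0.257 to 0.818). It did not pass either (edgeR, adjusted p = 0.55), and the interval does not allow for Rps27a having been picked for its small p. With these limits, the sum argues only against reads moving among these 4 genes as the whole origin. Copies under other names and reads left uncounted are outside the sum, so movement to or from them stays open. A shift of part of the reads may remain beside the 0.538, and an effect of treatment stays open and was not tested apart from it.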
